A study of Mus musculus with 15 samples.

How the data were processed

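Gene expression was measured in the scraped mucosa of the distal colon of female Balb/cJ mice on 1-colour Agilent arrays, with 1 mouse and 1 array per sample. The labels give 3 groups of 5 mice: water, dextran sodium sulfate (DSS) with vehicle, and DSS with filgotinib, a small-molecule inhibitor that prefers the kinase JAK1. The labels call the compound of the water group a vehicle control, whereas the design text gives these mice drinking water alone, so it stays open whether they were dosed with vehicle.

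Each scanner file holds, per the file headers, the intensity of every spot after background subtraction and detrending within the array by Agilent Feature Extraction 11.5.1.1, with no adjustment between arrays. The deposited table of the whole series holds log2 values of 32349 probes; its columns correlated with log2 of their own array at r between 0.9988 and 0.9997 across probes, its column medians lay between 8.841 and 8.859, and its values are not centred per gene. The normalization between arrays and the filter on probes behind the deposited log2 table are not given in the sources used here. The submitters' processing notes also name limma.

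The main values were log2 of the processed signal minus each array's 75th percentile. Control spots were left out, as were 101 probes with an outlier mark on an array, which left 56504 probes, and no spot was saturated. Of these probes, 32934 were named through an accession in the RefSeq gene table of GRCm38.p6, used for names only, 10211 had a file name that is a symbol of that table, 346 shared the file name of a matched probe, and 13013 kept the file's name, which can be old. A probe had to be well above background on at least 5 of the 15 arrays, and each gene was represented by its brightest such probe, which gave 22012 genes, 16210 of them in the table. Probes of a gene can disagree: among called genes with several probes, all probes had the same sign for 84.2% of genes in DSS against water, 78.4% in filgotinib against DSS vehicle and 64% in filgotinib with DSS against water.

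Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, in a single fit over all 15 arrays with the group as the factor, two-sided, with Benjamini-Hochberg adjustment over all genes. A gene was called at an adjusted p under 0.05, and "rose" and "fell" refer to such calls. A group whose 5 arrays all lacked signal well above background for a gene has only an upper bound there. The change is then given as at least N-fold, from the mean normalized log2 value of the bright group against the mean over the dim group's arrays of the larger of the probe's own value and the lowest value of any probe well above background on that array, together with the adjusted p of the fit.

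The design, the main tests, the 32 gene lists, the rule for named genes and the planned settings were fixed before the data were examined. Named genes are the 10 largest rises and 10 largest falls among called genes with an established symbol and no overlap between the 2 groups' values, 2 to 4 members of each list described, taken by the size of their change, and a fixed set of colitis and epithelial genes. Of that set, Cxcl9 and Il6 were not well above background on any array and have no value here. Changes were ranked by the fitted log2 fold change, background readings included. A gene given only as a bound can thus rank above one with a larger secure change. The lists cover interferon, STAT3 and JAK signalling, inflammatory mediators, immune cell types, epithelial cell types, cell cycle, stroma, barrier and metabolism, and were written from general knowledge of mouse colon. They were tested with camera at a preset correlation of 0.01 and with Benjamini-Hochberg adjustment over the lists of a comparison, beside camera with an estimated correlation, fry, a count of members adjusted over the list alone, and an exact two-sided permutation test of the per-mouse mean of each list. For the lists, the fixed design named camera with both correlations and the counts of members, but not this permutation test. A score of the DSS response was computed for each mouse from genes that DSS changed at least 2-fold, chosen without the array being scored if it belonged to the water or DSS vehicle group, and scaled so that the water mean is 0 and the DSS vehicle mean 1.

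The code was tested on simulated data over 22012 genes with 200 changed genes. In DSS against water it recovered 75% of genes changed 1.5-fold, 82.5% of those changed 2-fold and 100% of those changed 8-fold, and called 12 unchanged genes. In filgotinib against DSS vehicle it recovered 60%, 75% and 97.5% at the same folds, with 8 unchanged genes called. In filgotinib with DSS against water it recovered 62.5%, 80% and 97.5%, with 13 unchanged genes called. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

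Arrays lay on 6 slides scanned on 4 days. Slide 1 held water mice 1, 2 and 4, slide 2 DSS vehicle mice 1, 4 and 5 with filgotinib mice 1 and 2, slide 3 filgotinib mice 4 and 5, slide 4 water mice 3 and 5 with DSS vehicle mouse 2, and slides 5 and 6 DSS vehicle mouse 3 and filgotinib mouse 3. Slides 1 to 3 were scanned on day 1 and each other slide on a day of its own. Only slide 4 holds both water and DSS vehicle arrays and only slide 2 both groups given DSS, so a fit with the slide as a block takes each of these comparisons from that slide alone. Alternatives were quantile normalization, a median shift, normexp background correction, the deposited table, other filters on dim probes, the mean of probes, fits of 2 groups, robust and weighted fits, blocks for slide and replicate number, a 2-fold minimum, and leaving out each mouse. The scan day as a block, single scan days and slides, and leaving out 3 arrays that the scanner software marked for evaluation (DSS vehicle 3, filgotinib 4 and 5) were added after seeing the data.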

Results

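The study measured the colon mucosa of mice given DSS, as a model of chronic colitis, and of mice given water. DSS, a polymer that injures the colon epithelium when taken with drinking water, was given at 4% in 3 cycles of 4 days, each followed by a washout of 3 days, to mice 8 weeks old at the start. Filgotinib was given at 30 mg/kg by gavage each day. Mucosa was scraped from 30 mm of distal colon, and 100 ng of RNA was labelled for each array. There were 5 mice in each of the water, DSS vehicle and filgotinib groups, and n = 5 per group applies to every value unless stated. Between 50.2% and 62.1% of probes were well above background on an array. The 75th percentile of the signal lay between 684 and 813 in water mice, 570 and 667 in DSS vehicle mice and 552 and 663 in filgotinib mice, and the number of arrays limits the precision of every value.

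The first comparison asks what 3 cycles of DSS changed. Among genes whose values did not overlap between the groups, those with the largest rises included genes of matrix-degrading and mast cell proteases. Mmp10 was at least 18.7-fold higher (adjusted p = 0.000396), Mmp13 at least 10.1-fold (adjusted p = 0.000203) and Mmp3 at least 5.61-fold (adjusted p = 0.00445). Il1rl1, the receptor for interleukin 33, was at least 21.6-fold higher (adjusted p = 0.000341) and the neutrophil-attracting chemokine Cxcl5 at least 6.8-fold (adjusted p = 1.15e-05). The mast cell proteases Mcpt1 and Mcpt4 rose 22.9-fold and 21.0-fold (both adjusted p = 1.08e-05). Igfbp5 and Ifi202b rose 37.4-fold and 17.1-fold (adjusted p = 0.00598 and 0.00153). The largest falls included markers of crypt stem cells, with log2 fold changes of -5.55 ± 0.71 SE for Ascl2 (adjusted p = 0.000298), -3.82 ± 0.53 SE for Smoc2 (adjusted p = 0.000535) and at least a 9.02-fold fall for Lgr5 (adjusted p = 5.93e-10). Rgcc, Atp13a4, Bex4, Il33, Smpx, Bex1 and Pcdh17 were the others, with log2 fold changes from -4.94 for Rgcc to -3.26 for Pcdh17 and adjusted p up to 0.00094.

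Across all genes, 2369 were higher and 1851 lower in DSS vehicle than in water mice, 19.2% of those tested, and 396 and 479 of them changed at least 2-fold. The share of higher calls was 56.1%, against 37.9% when arrays were scaled to a common median. It was 48% with quantile normalization, 49.2% with normexp and 49% in the deposited table, so the balance of rises and falls depends on the scaling. The values of the 2 groups did not overlap for 3530 genes, 16% of those tested against 0.79% by chance. On slide 4, with 1 DSS vehicle and 2 water arrays, of the 10 largest such rises and 10 largest such falls, those well above background on at least 1 array of each group had log2 fold changes of 2.39 for Ifi202b to 4.76 for Mcpt1 and of -6.88 for Ascl2 to -3.05 for Bex1, but only 34 genes rose and 50 fell with the slide as a block. The genes named for slide 4 were picked for no overlap over all mice of the 2 groups, so their direction there was fixed in advance. Picking them by size also favours large values on that slide. Leaving out water mouse 4 left 1522 higher and 1307 lower calls.

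Most measured cell cycle genes and part of the stem cell genes fell after DSS. Of 35 measured cell cycle genes 33 fell and none rose (35 fell adjusted over the list alone), with a median log2 fold change of -1.31. The replication factors Mcm6 and Mcm5 fell 3.79-fold and 3.41-fold (adjusted p = 0.00382 and 0.00384), the mitotic kinase Aurkb 3.44-fold (adjusted p = 0.000535), and the proliferation marker Mki67 by 1.28 on the log2 scale (adjusted p = 0.00649). Of 21 measured crypt stem cell and Wnt target genes, 11 fell and 1 rose (12 and 2 adjusted over the list alone), with a median of -0.64, and Aqp1 of this list fell 4.77-fold (adjusted p = 0.014). Camera called both lists lower (adjusted p = 1.01e-24 and 9.15e-07), neither with an estimated correlation (both adjusted p = 0.193 with an estimated correlation). On slide 4 their medians were -1.88 and -0.82.

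Part of the interferon and STAT target genes rose. Of 33 interferon gamma-induced genes 16 rose and none fell (20 rose and 1 fell adjusted over the list alone). Their median was 0.60 (camera adjusted p = 1.28e-06, adjusted p = 0.244 with an estimated correlation). Ido1, which breaks down tryptophan, rose 10.7-fold (adjusted p = 0.00368) and the GTPase gene Ifi47 3.54-fold (adjusted p = 0.00874), while the chemokine Cxcl10 rose 2.88-fold (adjusted p = 0.0294). Of 31 type I interferon-induced genes 8 rose (12 adjusted over the list alone), with a median of 0.56 (camera adjusted p = 1.3e-05, adjusted p = 0.481 with an estimated correlation). Among them were Ifit2, up 4.23-fold, Ifi44 3.71-fold and Ifit3 2.87-fold (adjusted p = 0.0264, 0.0438 and 0.00491). Of 26 STAT3-induced genes 12 rose (16 adjusted over the list alone), with a median of 0.55 (camera adjusted p = 1.3e-05, adjusted p = 0.193 with an estimated correlation). They included the acute-phase gene Saa3, 15.6-fold (adjusted p = 0.000422), the feedback inhibitor Socs3, 5.18-fold (adjusted p = 0.000193), and Lcn2, 3.38-fold (adjusted p = 0.00863), whereas Reg3g at 3.78-fold did not pass (adjusted p = 0.102, and 0.0387 without filgotinib mouse 4). Of 22 JAK and STAT components 5 rose (7 adjusted over the list alone; camera adjusted p = 0.0108, adjusted p = 0.244 with an estimated correlation). Beside Socs3 these included Jak3 1.51-fold and Stat3 1.44-fold (adjusted p = 0.00301 and 0.00139), and Socs1 rose 1.39-fold (adjusted p = 0.0191), while Jak1 had a log2 fold change of 0.10 ± 0.07 SE (adjusted p = 0.322). Of 30 cytokines and receptors that signal through JAKs 11 rose and 2 fell (14 and 2 adjusted over the list alone; camera adjusted p = 0.00211, adjusted p = 0.244 with an estimated correlation). Il11 rose 7.11-fold (adjusted p = 0.00277).

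The interferon and STAT3 medians were smaller on slide 4, which holds 1 DSS vehicle mouse. Some calls near the threshold were lost when 1 mouse was left out. On slide 4 the median of the interferon gamma list was 0.21, that of the type I interferon list -0.03, and that of the STAT3 list 0.31. Calls were lost for Socs1 without water mouse 2 (adjusted p = 0.051) and Cxcl10 without water mouse 2, 4 or 5 or DSS vehicle mouse 3 or 4 (up to 0.076). They were also lost for Ifit2 without water mouse 1, 2, 4 or 5 or DSS vehicle mouse 1 or 4 (up to 0.0631), and Ifi44 without any water mouse, DSS vehicle mouse 1, 3, 4 or 5 or filgotinib mouse 1 (up to 0.0987).

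Some markers of several immune cell types rose. Of 11 mast cell markers 6 rose and 1 fell (6 and 1 adjusted over the list alone), with a median of 0.60 (camera adjusted p = 0.000958, adjusted p = 0.086 with an estimated correlation). The mast cell protease Mcpt2 was at least 3.56-fold higher (adjusted p = 7.3e-06). Of 17 neutrophil markers 7 rose (10 adjusted over the list alone; median 0.60, camera adjusted p = 0.000958, adjusted p = 0.193 with an estimated correlation). S100a9 rose 14.4-fold (adjusted p = 0.00608) while S100a8 at 1.86-fold did not pass (adjusted p = 0.335). Of 24 T and NK cell markers 7 rose (12 adjusted over the list alone; median 0.53, camera adjusted p = 8.58e-05, adjusted p = 0.37 with an estimated correlation). Gata3 rose 3.74-fold (adjusted p = 0.0133). Of 9 MHC class II genes 4 rose (6 adjusted over the list alone; median 1.17, camera adjusted p = 0.0037, adjusted p = 0.481 with an estimated correlation). Their activator Ciita rose 3.18-fold (adjusted p = 0.00749). Only 2 of 21 macrophage and monocyte markers rose, in the count over all genes and in that adjusted over the list alone, although the list median was 1.06 (camera adjusted p = 0.00152, adjusted p = 0.497 with an estimated correlation). B and plasma cell markers, with 3 of 18 higher (4 adjusted over the list alone), were not called (camera adjusted p = 0.448). Both eosinophil markers that passed, of 3 measured, fell (2 adjusted over the list alone), Siglecf 2.54-fold (adjusted p = 0.00139) and Alox15 at least 1.38-fold (adjusted p = 0.0016), with a list median of -1.34, or -0.46 with Alox15 at its bound (camera adjusted p = 0.0291, adjusted p = 0.193 with an estimated correlation). Of 22 inflammatory cytokines and chemokines 7 rose and 1 fell (9 and 1 adjusted over the list alone; median 0.43, camera adjusted p = 0.0183, adjusted p = 0.481 with an estimated correlation). Il1b rose 4.66-fold and Tnf 1.42-fold, and the alarmin Il33 fell 12.4-fold (adjusted p = 0.00981, 0.00154 and 0.000193). On slide 4 the medians were 0.77 for mast cell, 0.32 for neutrophil, 0.24 for T and NK cell, 0.23 for macrophage, 0.07 for MHC class II and 0.04 for inflammatory genes, while that of eosinophil markers would rest on Alox15, which has only a bound.

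Some secretory and endocrine genes of the epithelium changed, while the absorptive cell genes Slc26a3, Car4 and Aqp8 did not pass. Among 25 enteroendocrine and tuft cell genes 15 rose and 4 fell (16 and 4 adjusted over the list alone; median 0.62, camera adjusted p = 0.000105, adjusted p = 0.193 with an estimated correlation). The hormone genes Cck and Sst rose 10.8-fold and 3.20-fold and the granule gene Scg2 2.89-fold (adjusted p = 5.89e-06, 0.000193 and 1.53e-05), whereas the tuft cell genes Trpm5 and Gfi1b were at least 2.46-fold and 1.59-fold lower (adjusted p = 0.000198 and 0.00104). Among 26 goblet cell genes 12 rose and 1 fell (13 and 1 adjusted over the list alone; median 0.26, camera adjusted p = 0.000958, adjusted p = 0.481 with an estimated correlation). Itln1 rose 5.49-fold, Retnlb 3.84-fold and the mucin Muc2 1.27-fold (adjusted p = 0.00104, 0.0051 and 0.0176). Absorptive colonocyte genes were not called as a list (8 of 40 higher and 5 lower, 8 and 7 adjusted over the list alone; camera adjusted p = 0.572). Slc26a3, Car4 and Aqp8 had log2 fold changes of -0.23 ± 0.18, -0.31 ± 0.18 and -0.20 ± 0.17 SE (adjusted p = 0.386, 0.241 and 0.433), while the water channel Aqp4 rose 5.42-fold (adjusted p = 0.000323). Among 25 genes of regenerating epithelium 8 rose and 2 fell (11 and 2 adjusted over the list alone; camera adjusted p = 0.0747). Ly6a rose 6.37-fold and Emp1 4.47-fold (adjusted p = 0.000467 and 0.00139). On slide 4 the medians were 0.73 for the enteroendocrine and tuft list and 0.22 for the goblet list. The other probes of Itln1 and Aqp4 changed less, down to log2 fold changes of 0.78 and 0.11.

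Among 17 matrix metalloproteinases and inhibitors 8 rose and 1 fell (10 and 1 adjusted over the list alone; median 1.60, camera adjusted p = 0.000958, adjusted p = 0.481 with an estimated correlation). Fibroblast and matrix genes had a median of 1.38 (camera adjusted p = 0.00158, adjusted p = 0.564 with an estimated correlation), but only 3 of 29 rose and 0 passed adjusted over the list alone. Of these, Grem1 and Tnc (adjusted p = 0.0364 and 0.0252) each lost the call without any of several mice: water 2 or 3 or DSS vehicle 1, 4 or 5 for both, and for Grem1 also water 4 or 5 or DSS vehicle 3 (up to 0.0885). On slide 4 the 2 medians were 0.37 and 0.15. Smooth muscle (0 of 16 higher, 2 lower, camera adjusted p = 0.167), endothelial (0 of 19 called, 0.417), enteric neuron and glia (3 of 12 higher, 0.0564) and adipocyte lists (3 of 13 higher and 1 lower, 0.233) were not called, with the same numbers adjusted over the list alone. Within them, the neuronal genes Ret and Uchl1 rose 4.95-fold and 2.65-fold (adjusted p = 1.85e-05 and 0.000162) and Cidea 3.16-fold (adjusted p = 0.000193), while Des, a muscle filament gene, was 4.33-fold higher without passing (adjusted p = 0.151).

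Some barrier and metabolic genes changed. Of 27 antimicrobial and barrier defence genes 8 rose and 5 fell (13 and 7 adjusted over the list alone; camera adjusted p = 0.105). The protease inhibitor Slpi rose 9.96-fold and the phospholipase Pla2g2a 6.67-fold (adjusted p = 7.87e-05 and 0.000766). Tight junction genes were not called (2 of 24 higher, 3 lower, camera adjusted p = 0.949), though the pore-forming claudin Cldn2 fell 4.41-fold (adjusted p = 0.00116). Of 28 fatty acid oxidation and ketone genes 7 rose (9 adjusted over the list alone; median 0.18, camera adjusted p = 0.026, adjusted p = 0.564 with an estimated correlation). Xenobiotic and steroid metabolism genes (1 of 31 higher, 5 lower, camera adjusted p = 0.334) included the carboxylesterase Ces1d, down 4.52-fold (adjusted p = 0.00575). Squamous epithelium markers (2 of 21 higher, 1 lower, 0.287) included Krt14, up 3.72-fold (adjusted p = 0.00148), while Krt5 had a log2 fold change of 0.45 ± 0.84 SE (adjusted p = 0.742). Immediate early and heat shock genes (4 of 20 higher, 0.167) included Egr2, up 2.55-fold (adjusted p = 0.0102), and 0 of 20 unfolded protein response genes were called (0.772). For the tight junction, xenobiotic, squamous, immediate early and unfolded protein response lists the same numbers passed adjusted over the list alone.

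Camera called 19 of the 32 lists in this comparison, 16 higher and 3 lower, and 0 with an estimated correlation, for which the lowest adjusted p was 0.086 and 7 lists had an unadjusted p under 0.05. Fry, which asks whether the genes of a list move one way on balance, called 20. The list median, mean and test differed in sign for absorptive colonocyte, tight junction and unfolded protein response genes. Of 100 splits of the 10 mice, the real one included, 11 called as many lists, so the number of list calls by camera does not stand out from such splits. In the exact permutation test of per-mouse list means, several lists reached the smallest p that 5 against 5 mice allow (p = 0.00794, 0.0159 after adjustment over the 32 lists). Among the lists that camera called, these were the interferon gamma, STAT3, JAK and STAT component, JAK cytokine, neutrophil, T and NK cell, mast cell, eosinophil, enteroendocrine and tuft, stem cell, cell cycle, metalloproteinase and fatty acid oxidation lists. Among the others, they were the squamous, neuron and glia, and antimicrobial lists. The inflammatory, MHC class II and goblet lists passed with an adjusted exact p = 0.0268, the regenerating epithelium list with 0.0381 and the type I interferon list with 0.0483. The fibroblast and macrophage lists, which camera called, did not pass (adjusted exact p = 0.0692 and 0.0879).

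The second comparison asks what filgotinib changed in mice given DSS. Among genes whose values did not overlap between the groups, the largest falls by fitted change were those of Saa3, Cxcl5, Mptx1, Mptx2, Mcpt2, Ifit2, Itln1, Steap4, Cck and Galr1. The acute-phase gene Saa3 had a log2 fold change of -3.41 ± 0.54 SE (10.7-fold lower, adjusted p = 0.00252), Cxcl5 of -3.20 ± 0.39 SE (adjusted p = 0.000575), and the pentraxin genes Mptx1 and Mptx2 of -3.10 ± 0.66 and -2.99 ± 0.61 SE (adjusted p = 0.0101 and 0.00854). Mcpt2 was at least 1.97-fold lower (adjusted p = 0.000218) and Galr1 at least 1.24-fold (adjusted p = 0.00195). Ifit2 fell 6.56-fold, Itln1 6.13-fold, the metalloreductase Steap4 5.12-fold and Cck 4.73-fold (adjusted p = 0.0121, 0.00157, 0.0046 and 0.00029). The largest rises among such genes were 5.32-fold for Smpx, 4.97-fold for the albumin gene Alb, 4.96-fold for Slurp1, 4.87-fold for Calcb, 4.45-fold for the histone gene H2bc23, 4.24-fold for Hpn, 4.23-fold for Rgs13, 4.13-fold for the urea cycle enzyme Otc and 3.76-fold for Gp2 (adjusted p from 0.00112 for Otc to 0.0206 for Alb), and Ugt2b35 was at least 1.21-fold higher (adjusted p = 0.000537). The call of Alb was lost without DSS vehicle mouse 1 (adjusted p = 0.0586).

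In all, 1494 genes were higher and 998 lower with filgotinib than with vehicle, 11.3% of those tested, and 203 changed at least 2-fold in each direction. The share of higher calls was 60%, against 73.6% with arrays scaled to a common median. It was 56.1% with quantile normalization, 54.1% with normexp and 54.9% in the deposited table. The values of the groups did not overlap for 1759 genes, 8% against 0.79% by chance. On slide 2, with 3 DSS vehicle and 2 filgotinib arrays, of the 10 largest such rises and 10 largest such falls, those well above background on at least 1 array of each group had log2 fold changes of 1.74 for Rgs13 to 2.80 for Smpx and of -3.45 for Saa3 to -2.17 for Steap4. Since such genes were picked for no overlap over all mice of the 2 groups, their direction on slide 2 was fixed in advance. The choice by size also favours large values there. With the slide as a block 234 genes rose and 203 fell. Leaving out DSS vehicle mouse 1 left 790 higher and 525 lower calls, DSS vehicle mouse 5 left 891 and 682, filgotinib mouse 2 left 856 and 648, and filgotinib mouse 5 left 828 and 571.

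A minority of the measured interferon and JAK pathway genes fell with filgotinib. Of the type I interferon-induced genes 8 of 31 fell (15 adjusted over the list alone), with a median of -0.66 (camera adjusted p = 8.72e-10, adjusted p = 0.476 with an estimated correlation). Among them, Ifi44 fell 5.80-fold and Ifit3 3.37-fold (adjusted p = 0.0187 and 0.00468). Of the interferon gamma-induced genes 7 of 33 fell and 1 rose (13 and 1 adjusted over the list alone), with a median of -0.48 (camera adjusted p = 9.04e-07, adjusted p = 0.346 with an estimated correlation). Among them, Gbp3 fell 2.38-fold (adjusted p = 0.0187) and Ciita 2.41-fold (adjusted p = 0.0418). Of the STAT3-induced genes 4 of 26 fell (4 adjusted over the list alone; median -0.32, camera adjusted p = 0.00187, adjusted p = 0.346 with an estimated correlation). Of JAK and STAT components 5 of 22 fell (7 fell and 1 rose adjusted over the list alone; median -0.20, camera adjusted p = 0.000861, adjusted p = 0.241 with an estimated correlation). Socs3 fell 2.99-fold (adjusted p = 0.00489) and Jak3 1.40-fold (adjusted p = 0.0152). Log2 fold changes that did not pass were -0.22 ± 0.13 SE for Socs1 (adjusted p = 0.287), -0.63 ± 0.45 SE for Cxcl10 (adjusted p = 0.381) and 0.09 ± 0.07 SE for Jak1 (adjusted p = 0.417). Cytokines and receptors that signal through JAKs (1 of 30 higher, 2 lower, the same numbers adjusted over the list alone) missed the threshold (camera adjusted p = 0.052). Il11 fell 5.11-fold (adjusted p = 0.0128). On slide 2 the medians were -0.67 for the type I interferon, -0.61 for the interferon gamma, -0.32 for the STAT3 and -0.27 for the component list. The call of Ciita was lost without any of 8 mice (water 1 or 2, DSS vehicle 1, 3, 4 or 5, or filgotinib 1 or 5, adjusted p up to 0.0924).

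Some mast cell markers and a few other immune markers fell. Of 11 mast cell markers 5 fell and 1 rose (7 and 2 adjusted over the list alone), with a median of -0.65, or -0.35 with genes below background at their bounds (camera adjusted p = 0.00393, adjusted p = 0.127 with an estimated correlation). Mcpt1 and Mcpt4 fell 4.11-fold and 4.01-fold (adjusted p = 0.005 and 0.00473). Il1rl1 fell too (adjusted p = 0.013), by an uncertain amount, as it was well above background on 2 of 5 filgotinib arrays. Of 17 neutrophil markers 2 fell (3 adjusted over the list alone; median -0.28, camera adjusted p = 0.00142, adjusted p = 0.295 with an estimated correlation). S100a9 fell 8.69-fold (adjusted p = 0.028), a call lost without DSS vehicle mouse 1 or 5 or filgotinib mouse 1 (up to 0.0618). S100a8 did not pass (adjusted p = 0.096). Of 24 T and NK cell markers 2 fell (4 adjusted over the list alone; median -0.35, -0.31 with bounds, camera adjusted p = 0.000694, adjusted p = 0.526 with an estimated correlation). Macrophage markers had a median of -0.55 with 0 of 21 called (camera adjusted p = 0.00328, adjusted p = 0.624 with an estimated correlation). B and plasma cell (1 of 18 lower, camera adjusted p = 0.17), MHC class II (1 of 9 lower, 0.124), eosinophil (1 of 3 higher, Siglecf 2.15-fold with adjusted p = 0.00746, 0.27 for the list) and inflammatory cytokine lists (2 of 22 higher, 5 lower, 0.115) were not called. Adjusted over the list alone, 3 inflammatory genes were higher and 7 lower, 2 eosinophil markers higher and 1 lower, and the other 2 lists kept their numbers. Tnf fell 1.26-fold (adjusted p = 0.0224), a call lost without DSS vehicle mouse 1 or filgotinib mouse 1 (up to 0.0567). Lcn2 (-1.08 ± 0.40 SE, adjusted p = 0.0931, and 0.00999 without DSS vehicle mouse 2) and Il1b (-1.49 ± 0.52 SE, adjusted p = 0.0758, and 0.0395 without filgotinib mouse 2) did not pass. On slide 2 the medians were -0.38 for neutrophil, -0.31 for T and NK cell and -1.004 for macrophage markers, while that of mast cell markers would rest on a gene without signal above background in 1 group.

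Part of the cell cycle genes rose with filgotinib, and part of the enteroendocrine and tuft cell genes fell. Of 35 cell cycle genes 22 rose and none fell (22 rose adjusted over the list alone), with a median of 1.05 (camera adjusted p = 1.15e-10, adjusted p = 0.517 with an estimated correlation). Among them, Ccnb1 rose 2.97-fold and Ttk 2.80-fold (adjusted p = 0.00236 and 0.00332) and Mki67 2.22-fold (adjusted p = 0.0186, and 0.051 without DSS vehicle mouse 1). Crypt stem cell and Wnt target genes were not called (1 of 21 higher, 1 adjusted over the list alone; camera adjusted p = 0.674). The list median was -0.07, and 10 of the 21 log2 fold changes were positive. The log2 fold change was 1.33 for Smoc2, which did not pass (adjusted p = 0.119), and 1.14 for Aqp1. With the slide as a block, Smoc2 was higher (1.73, adjusted p = 0.00939). Ascl2 had a log2 fold change of -0.09 ± 0.71 SE (adjusted p = 0.949), and Lgr5 was not well above background on any array of either group. Of 25 enteroendocrine and tuft cell genes 15 fell and 4 rose (17 and 4 adjusted over the list alone), with a median of -0.67 (camera adjusted p = 3.44e-08, adjusted p = 0.127 with an estimated correlation). Scg2 fell 2.25-fold and Sst 2.03-fold (adjusted p = 0.000378 and 0.007), and the tuft cell genes Gfi1b and Trpm5 were at least 1.80-fold and 1.25-fold higher (adjusted p = 0.00109 and 0.0119). Of 26 goblet cell genes 4 fell (4 adjusted over the list alone; median -0.10, camera adjusted p = 0.0391, adjusted p = 0.63 with an estimated correlation). Retnlb fell 4.27-fold (adjusted p = 0.0062) and Muc2 had a log2 fold change of -0.11 ± 0.09 SE (adjusted p = 0.466). Of 40 absorptive colonocyte genes 4 rose (4 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.529), and Slc26a3, Car4 and Aqp8 had log2 fold changes of 0.01 ± 0.18, -0.02 ± 0.18 and 0.19 ± 0.17 SE (adjusted p of at least 0.5). On slide 2 the medians were 0.83 for cell cycle, -0.54 for enteroendocrine and tuft and -0.20 for goblet genes.

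Part of the protease genes that DSS raised fell with filgotinib, while Mmp3 had a log2 fold change of -1.75 ± 0.93 SE (adjusted p = 0.235). Of 17 matrix metalloproteinases and inhibitors 4 fell (5 adjusted over the list alone), with a median of -1.05 (camera adjusted p = 0.000694, adjusted p = 0.527 with an estimated correlation). Mmp10 and Mmp13 fell (adjusted p = 0.00493 and 0.00267), but each was well above background on only 1 of 5 filgotinib arrays, so the size of their falls is uncertain. Fibroblast and matrix genes had a median of -1.12 (camera adjusted p = 0.000766, adjusted p = 0.63 with an estimated correlation), yet 1 of 29 fell and 0 passed adjusted over the list alone. Of 12 enteric neuron and glia markers 3 fell (3 adjusted over the list alone; median -0.23, camera adjusted p = 0.00958, adjusted p = 0.295 with an estimated correlation). Ret fell 2.57-fold and Uchl1 2.23-fold (adjusted p = 0.00195 and 0.00143). Of 27 antimicrobial and barrier genes 6 fell and 3 rose (9 and 5 adjusted over the list alone; camera adjusted p = 0.025, adjusted p = 0.476 with an estimated correlation). Slpi fell 3.21-fold (adjusted p = 0.00911). Of 31 xenobiotic and steroid metabolism genes 8 rose and 1 fell (9 and 2 adjusted over the list alone; median 0.18, camera adjusted p = 0.0391, adjusted p = 0.533 with an estimated correlation). Ces1d rose 4.49-fold and the glutathione transferase Gsta3 3.66-fold (adjusted p = 0.0101 and 0.0181). The regenerating epithelium (1 of 25 higher, 4 lower, camera adjusted p = 0.0746), squamous (2 of 21 higher, 2 lower, 0.238), smooth muscle (0 of 16, 0.394), endothelial (0 of 19, 0.38), adipocyte (1 of 13 lower, 0.77), tight junction (0 of 24, 0.931), fatty acid oxidation (2 of 28 higher, 0.121), immediate early and heat shock (1 of 20 lower, 0.296) and unfolded protein response lists (2 of 20 higher, 1 lower, 0.17) were not called. Adjusted over the list alone, 2 regenerating epithelium genes were higher and 4 lower, 0 fatty acid oxidation genes passed, 3 unfolded protein response genes were higher and 1 lower, and the other lists had the same numbers. On slide 2 the medians were -1.45 for metalloproteinase, -2.35 for fibroblast, -0.30 for neuron and glia, -0.28 for antimicrobial and 0.28 for xenobiotic genes. Slide 2 holds only filgotinib mice 1 and 2, and the per-mouse fibroblast mean varied widely within the filgotinib group (SD 1.557).

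Camera called 16 of 32 lists, 2 higher and 14 lower, and 0 with an estimated correlation (lowest adjusted p = 0.127, 5 lists at an unadjusted p under 0.05), while fry called 11. The list median, mean and test differed in sign for stem cell, adipocyte and tight junction genes. Of 100 splits of the 10 mice 25 called as many, so the number of these list calls too does not stand out from such splits. In the exact permutation test of per-mouse means, the JAK and STAT component, mast cell and enteroendocrine and tuft lists reached p = 0.00794, the smallest possible, but none passed after adjustment over the 32 lists (lowest adjusted p = 0.0846).

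**Figure D1:**
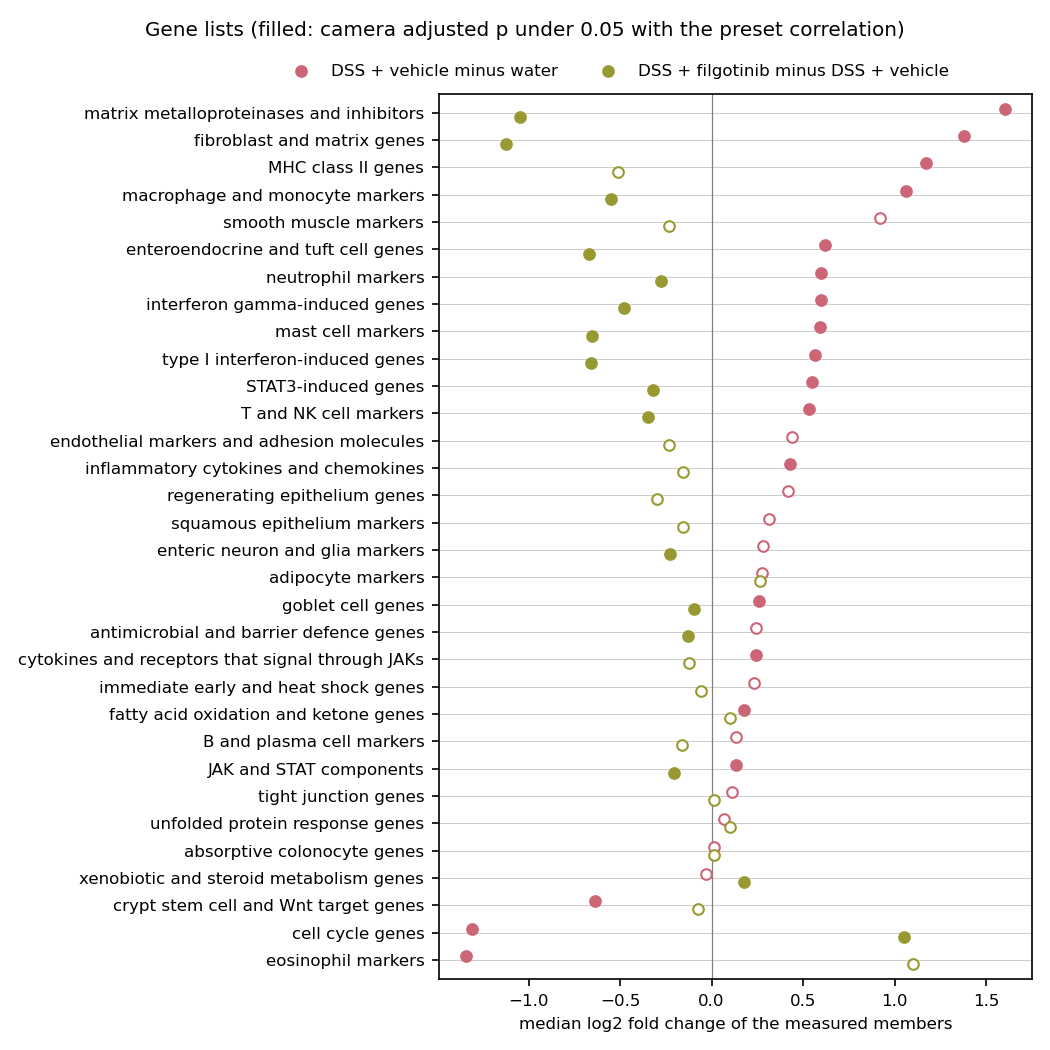
Median log2 fold change (x axis) of the measured members of each of the 32 gene lists (y axis) in DSS vehicle against water mice and in filgotinib against DSS vehicle mice. Filled points passed camera at the preset correlation, as for cell cycle genes at -1.31 and 1.05, and none passed with an estimated correlation.

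**Figure D2:**
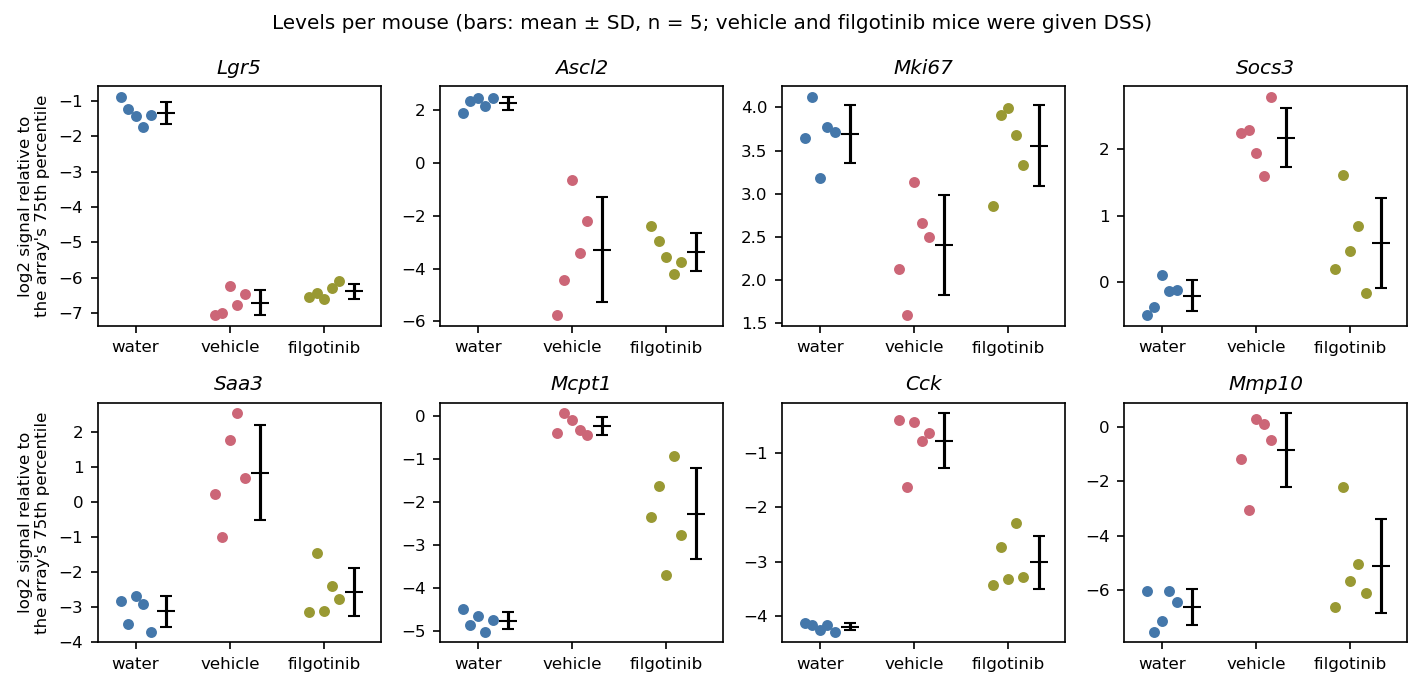
Log2 signal relative to each array's 75th percentile (y axis) of 8 genes in each mouse by group (x axis), with bars for the mean ± SD of 5 mice. Lgr5 and Ascl2 were low in both groups given DSS, whereas Saa3, Mcpt1, Cck and Mmp10 were lower with filgotinib than with vehicle.

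The third comparison asks what still differed from water mice under filgotinib. Part of the stem cell and Wnt target genes were still lower: 9 of 21 were lower and none higher (11 lower adjusted over the list alone), with a median log2 fold change of -0.74 (camera adjusted p = 3.25e-11, adjusted p = 0.168 with an estimated correlation). Ascl2 was 49.9-fold lower, Lgr5 at least 7.43-fold and Smoc2 5.64-fold (adjusted p = 0.00215, 1.39e-09 and 0.0162). Of 35 cell cycle genes 9 were lower (12 adjusted over the list alone; median -0.28, camera adjusted p = 1.72e-07, adjusted p = 0.996 with an estimated correlation), including Mcm6, 3.21-fold (adjusted p = 0.0193, and 0.0515 without filgotinib mouse 5), while Mki67 had a log2 fold change of -0.13 ± 0.28 SE (adjusted p = 0.8). Mast cell markers (3 of 11 higher, 6 adjusted over the list alone; median 0.64, camera adjusted p = 0.0311, adjusted p = 0.168 with an estimated correlation) included Mcpt1, 5.59-fold higher (adjusted p = 0.00406). Part of the fatty acid oxidation and ketone genes were higher (9 of 28, 14 adjusted over the list alone; median 0.29, or 0.25 with bounds, camera adjusted p = 0.000348, adjusted p = 0.996 with an estimated correlation). Ido1 was 8.50-fold higher (adjusted p = 0.0168), Pla2g2a 5.87-fold (adjusted p = 0.00527) and Krt14 2.82-fold (adjusted p = 0.0148), and Cldn2 was 2.94-fold lower (adjusted p = 0.017).

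In this comparison 1414 genes were higher and 750 lower, 9.8% of those tested, with 65.3% of calls higher against 48.8% under 3 of the other scalings. No slide holds both groups. With the slide as a block, linked only through the DSS vehicle arrays, 0 genes were higher and 2 lower (1795 at an unadjusted p under 0.05), and the 4 list medians were -0.72 for stem cell, -0.92 for cell cycle, 0.45 for mast cell and 0.39 for fatty acid oxidation genes. Leaving out water mouse 2, 4 or 5 left 640, 543 or 468 higher calls, and leaving out filgotinib mouse 1, 4 or 5 left 929, 735 or 438. Camera called 4 lists, and 0 with an estimated correlation (2 at an unadjusted p under 0.05, 4 by fry), and 89 of 100 splits of the 10 mice called as many.

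Changes under filgotinib ran against changes under DSS. Of the 2492 genes that filgotinib changed, 1207 had been changed by DSS in the opposite direction. Of these, 533 were raised and then lowered and 674 lowered and then raised, and 7 genes changed in the same direction. Independent lists of these sizes would share 233 opposed genes, and simulated groups with no effect that shared the DSS vehicle arrays gave a median of 0 and at most 1 in 100 simulations, a value that leaves out what shared arrays add when effects are present. The fold changes correlated at r = -0.74 across genes, which are not independent replicates, against -0.538 simulated from the shared arrays alone, and their covariance was -0.141 against -0.02 simulated. With the DSS vehicle arrays split 3 and 2 between the comparisons, the 20 assignments gave 153 to 601 opposed genes (median 353.5, against 30.5 for independent lists), with r from -0.638 to -0.455. Leaving out DSS vehicle mouse 1 left 696 opposed genes, and with the slide as a block there were 42. When each comparison was fitted on its own arrays, few genes were called for filgotinib and the opposed genes numbered 0 to 193 (median 6). Between effects taken within slide 4 and within slide 2, r was -0.403, and 4 of 30 relabellings of those arrays gave one as low.

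**Figure D3:**
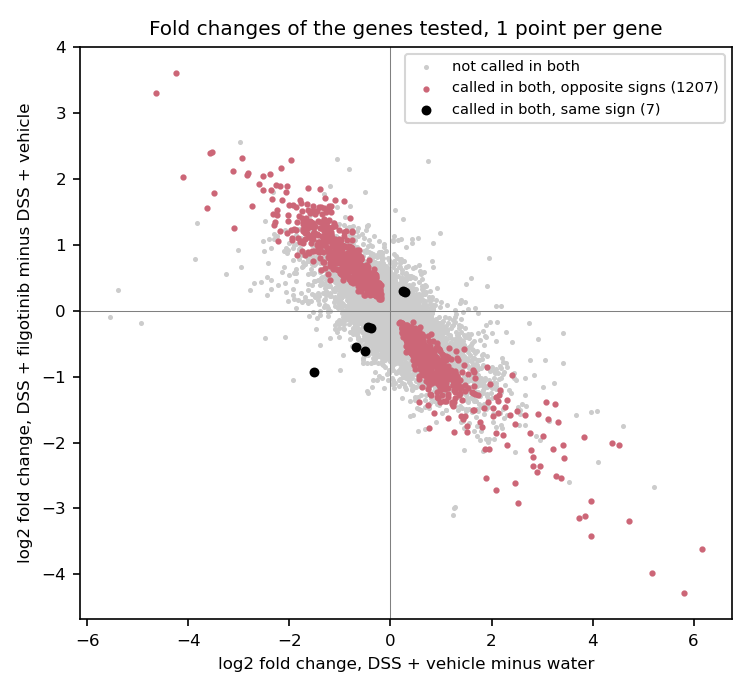
Log2 fold change of each gene tested in DSS vehicle against water mice (x axis) and in filgotinib against DSS vehicle mice (y axis), 1 point per gene. The 1207 genes called in both with opposite signs lie in the upper left and lower right, and the 7 called with the same sign are drawn in black; both axes use the same DSS vehicle arrays.

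The per-mouse DSS score used 396 raised and 479 lowered genes for filgotinib mice and 717 to 880 genes for each other mouse. It was 0 ± 0.104 SD in water mice, 1 ± 0.087 SD in DSS vehicle mice and 0.395 ± 0.129 SD in filgotinib mice. Filgotinib mice lay between 0.29 and 0.611, below all DSS vehicle mice (0.907 to 1.134) and above all water mice (-0.151 to 0.128). The difference of -0.605 from DSS vehicle mice and that from water mice each gave p = 0.00794 in an exact two-sided permutation test, the smallest that 252 splits allow. On scan day 1, with DSS vehicle mice 1, 4 and 5 and filgotinib mice 1, 2, 4 and 5, the difference was -0.56. Its exact permutation p = 0.0286 is the smallest that these mice allow. On slide 2 the difference was -0.704, where 3 against 2 mice cannot reach a p under 0.1.

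**Figure D4:**
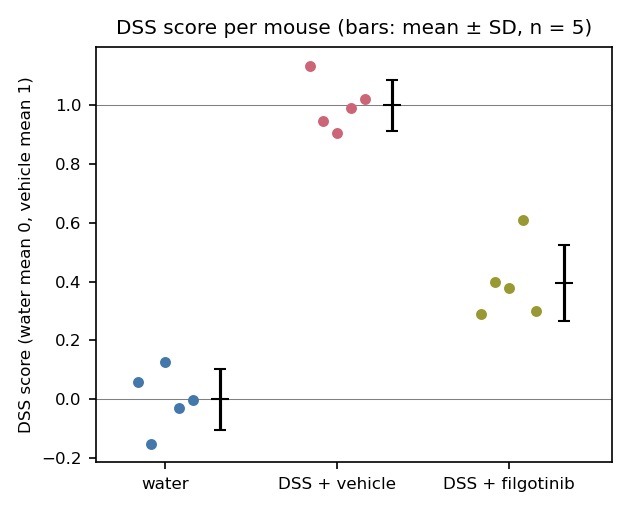
DSS score of each mouse (y axis, scaled to a water mean of 0 and a DSS vehicle mean of 1) by group (x axis), with bars for the mean ± SD of 5 mice. The 5 filgotinib mice lie between 0.29 and 0.611, apart from both other groups.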

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

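Of the tests in this part, those of the epithelial share, of cycling cells, of scan days and of slides for the stem cell pattern were chosen only after the result was seen.

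Some values lay far from the other mice of their group, judged by the gap to the nearest mouse as a share of the group's range. This gap was wide in 14 of 390 groups of 5 values, 3.6%, whereas chance gives about 1 in 20, and 4 of the 14 were in DSS vehicle mouse 2. In that mouse, on the scale of log2 signal relative to the 75th percentile, Mmp3 was at -5.60 against -2.14 to -1.60 in the other 4 (gap 0.867), Mmp13 at -3.88 against -1.56 to -0.90 (0.779), Smoc2 at -4.13 against -1.49 to -1.05 (0.858) and Socs1 at -0.46 against -0.20 to -0.15 (0.83). Its lower Mmp13 and Mmp3 go against the rise after DSS, and its lower Smoc2 goes with the fall.

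The type I interferon list mean of filgotinib mouse 5 was -0.97 relative to water, against -0.04 to 0.19 in the other filgotinib mice (0.804), so this mouse carries part of that list's fall. In water mouse 1, Mmp13 was at -5.38 against -7.47 to -7.08 (0.813), a gap among background readings, since no water array had signal well above background for it. Also in water mouse 1, Alb at 1.29 against -1.85 to -1.52 (0.897) and Il11 at -4.62 against -3.84 to -3.63 (0.788). In water mouse 5, Slurp1 was at -0.09 against -1.94 to -1.47 (0.748) and Gfi1b at -3.09 against -4.13 to -3.91 (0.781). Bex4 and Bex1 were low in filgotinib mouse 4, at -3.51 against -1.10 to -0.17 (0.721) and -2.10 against -0.40 to 0.27 (0.717), and Bex1 was low in DSS vehicle mouse 4, at -2.85 against -2.17 to -1.94 (0.743). Il11 was at -1.76 in filgotinib mouse 2 against -4.02 to -3.67 (0.844). No cause was tested for these values.

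Crypt stem cell and Wnt target genes were low in both groups given DSS, with scores of -1.22 ± 0.18 SE under vehicle and -1.18 ± 0.14 SE under filgotinib relative to water (exact permutation p = 0.00794 for each). A smaller share of epithelial cells as a whole was argued against. The score of absorptive colonocyte and tight junction genes moved by 0.073 ± 0.091 SE with DSS (exact permutation p = 0.444). That score does not measure the share of crypt cells alone. Under filgotinib the cell cycle score rose relative to the stem cell score by 0.772 ± 0.235 SE (exact permutation p = 0.0317). This argues against fewer cycling cells as the whole cause in filgotinib mice. In DSS vehicle mice the mean cell cycle and stem cell scores were both low, -1.284 and -1.223 relative to water. Fewer cycling cells therefore stay open there. Scan days were argued against, as the list median was -0.634 within scan day 1 and -0.669 with the day as a block, against -0.639 in all arrays. Slides cannot be told apart from the groups: the DSS coefficient with the slide as a term was -1.64 ± 0.247 SE but rests on the 1 DSS vehicle and 2 water arrays of slide 4, and for that reason an earlier criterion that took slides and days together was set aside. That DSS itself lowered these genes stays open beside the slides and fewer cycling cells, and was not tested apart from them.

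The metalloproteinase list was higher after DSS by its per-mouse mean (adjusted exact p = 0.0159), while the fibroblast list, with 3 of 29 genes called, did not pass (adjusted exact p = 0.0692), and more stroma in the scraped mucosa is a possible explanation. With the endothelial score as a term, the DSS coefficient of the metalloproteinase score went from 1.91 ± 0.51 SE to 1.472 ± 0.212 SE. This argues against more endothelium as the whole cause. The endothelial score did not differ between DSS vehicle and water mice (exact permutation p = 0.333) and does not measure fibroblasts. More stroma of other kinds therefore stays open for this list. For the fibroblast list the DSS coefficient went from 1.25 ± 0.724 SE to 0.626 ± 0.263 SE, so more stroma cannot be told apart from a rise in these genes. Differences between slides stay open for both, since the list medians on slide 4 were 0.371 and 0.145, but these rest on DSS vehicle mouse 2, whose scores were the lowest of its group (0.823 against 1.577 to 2.614 and 0.125 against 1.176 to 2.434). That DSS itself raised the genes within stromal cells was not tested.

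Changes under filgotinib ran opposite to the changes under DSS, and both comparisons use the DSS vehicle arrays. These shared arrays as the whole cause were argued against: with the arrays split between the comparisons, the correlation across genes stayed at or below -0.455 in all 20 assignments. Differences between slides cannot be told apart from the groups, since the correlation of effects within slide 4 and within slide 2, which share no array, was -0.403, but 4 of 30 relabellings of so few arrays gave one as low, down to -0.558. A partial reversal of the DSS response by filgotinib is a candidate explanation.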

How the results depend on the processing

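The scan-day and single-slide settings and the one without arrays marked for evaluation were chosen after seeing the data.

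The DSS score difference of -0.605 lay between -0.671 and -0.559 when 1 mouse was left out, with exact permutation p = 0.00794 each time and under every setting chosen before the data were examined that gave a score. It was -0.56 on scan day 1 and -0.68 without the arrays marked for evaluation. Both gave an exact permutation p = 0.0286, the smallest that their fewer mice allow. On slide 2 the difference was -0.704, where 3 against 2 mice allow no p under 0.1.

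Leaving out 1 mouse gave 1522 to 2638 genes higher and 1307 to 2007 lower in DSS against water, 790 to 1842 and 525 to 1218 in filgotinib against DSS vehicle, 438 to 1919 and 307 to 967 in filgotinib with DSS against water, and 696 to 1444 opposed genes. The lowest counts came without water mouse 4, DSS vehicle mouse 1, filgotinib mouse 5 and DSS vehicle mouse 1.

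Filgotinib with DSS against water moved most: 585 genes were higher with quantile normalization, 678 with normexp, 600 in the deposited table and 732 with the mean of probes. A median shift gave 956 higher in DSS against water, 545 lower in filgotinib against DSS vehicle, and 254 higher and 267 lower in filgotinib with DSS against water. Array weights gave 3599 higher in DSS against water and 2150 in filgotinib with DSS against water. The cause was not tested. With no filter on dim probes, 693 were higher and 536 lower with filgotinib than with vehicle, 7916 and 1137 in filgotinib with DSS against water, and 691 opposed. The 75th percentile that the scaling subtracts was higher in water mice, with a mean log2 of 9.583. It was 9.228 in DSS vehicle and 9.234 in filgotinib mice, so water values were lowered more. How far this accounts for these counts was not tested. Fits of only the 2 groups, with fewer arrays, gave 754 and 522 with filgotinib, 651 and 428 against water, and 768 opposed. A 2-fold minimum gave 396 and 479, 203 and 203, and 60 and 129 in the 3 comparisons, and 285 opposed, and it counts fewer genes by construction.

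With the slide as a fixed block 34 genes were higher and 50 lower in DSS against water, 234 and 203 in filgotinib against DSS vehicle, 0 and 2 in filgotinib with DSS against water, and 42 opposed, with few arrays on shared slides. As a random block it gave 899 and 497 in filgotinib with DSS against water. Slide 2 alone gave 2 higher and 1 lower with filgotinib (4398 at an unadjusted p under 0.05), and slide 4 alone 0 and 0 with limma in DSS against water (2526), its lone DSS vehicle array assumed to vary like the others. Scan day 1 alone gave 703 and 916 in DSS against water, 367 and 329 in filgotinib with DSS against water, and 635 opposed. Without the arrays marked for evaluation, filgotinib raised 941 genes, and 101 and 122 differed from water. These settings have fewer arrays. Opposed genes numbered 153 to 601 (median 353.5) with the DSS vehicle arrays split 3 and 2.

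For lists that passed in the main or the other setting, the direction of the test turned only with slides. Among lists that passed in neither, fry turned some, such as absorptive colonocyte genes in DSS against water. With the slide as a block, the DSS medians of the type I interferon (-0.031), inflammatory (0.043), MHC class II (0.069), fibroblast (0.145) and metalloproteinase lists (0.371) shrank, and their tests, in the other direction, did not pass (adjusted p of at least 0.658). Against water under filgotinib the interferon gamma (-0.178), macrophage (-0.727), smooth muscle (-1.636), metalloproteinase (-0.655) and endothelial medians (-1.424) turned negative. Camera at the preset correlation called these lists lower there, from the few arrays on shared slides. On slide 4 alone the B cell (-0.102), smooth muscle (-0.74) and endothelial medians (-0.735) turned negative, and the type I interferon (-0.031), inflammatory (0.043), MHC class II (0.069) and fibroblast medians (0.145) shrank to near 0. No named gene reversed under quantile normalization, normexp, the deposited table, the mean of probes or leaving out 1 mouse. On slide 4, DSS against water turned for Grem1 (3.42 in all arrays, -0.08 on the slide), Des (2.12 and -0.67) and S100a8 (0.90 and -0.57), of which only Grem1 had been called.

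Replicate numbers did not pair the mice (5 of 15 same-number pairs correlated above 0.1, from -0.516 to 0.532). With the number as a block anyway, 1841 genes were higher and 1571 lower in DSS against water, 930 and 678 in filgotinib against DSS vehicle, 463 and 325 in filgotinib with DSS against water, and 882 were opposed.

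Signal over background limits every change given as a bound. In DSS against water these include Lgr5, Mmp10, Mmp13, Mmp3, Il1rl1, Cxcl5, Mcpt2, Alox15, Trpm5 and Gfi1b, and with filgotinib against DSS vehicle they include Mcpt2, Galr1, Ugt2b35, Trpm5 and Gfi1b. Cxcl9 and Il6 have no value.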

Other observations

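The overlaps of the comparisons that share water or filgotinib arrays were tests chosen only after the gene counts were seen.

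Random splits of the mice did not reach the numbers of genes called. Of 100 splits of the 10 mice of each comparison, the real one included, only the real 1 gave as many genes: 4220 in DSS against water (highest other split 1), 2492 in filgotinib against DSS vehicle (242) and 2164 in filgotinib with DSS against water (32). For the 1207 opposed genes, 1 of 100 splits of the filgotinib and DSS vehicle mice gave as many, the real one (highest other 207). Such splits mix the slides, which partly follow the groups, so they cannot exclude differences between slides. Mixed splits also carry the real group difference as spread within their groups. With the slide as a block, 437 genes were called in filgotinib against DSS vehicle.

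Chance cannot be excluded for the numbers of gene lists called by camera. As many lists were called in 11 of 100 splits for DSS against water (real 19, highest other 23), in 25 of 100 for filgotinib against DSS vehicle (16 and 25) and in 89 of 100 for filgotinib with DSS against water (4 and 22). Single lists rest on the exact permutation tests of per-mouse means, which the fixed design did not name for the lists.

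DSS against water and filgotinib with DSS against water share the water arrays. They shared 967 genes called with the same sign, 592 higher and 375 lower, and 9 with opposite signs, where independent lists would share 215.2 of the same sign and simulated groups without an effect shared 0 at most in 100 simulations, which leaves out what shared arrays add when effects are present. With the water arrays split 3 and 2 between the comparisons, 20 assignments gave 8 to 166 (median 86, against 8.8 for independent lists). The covariance of fold changes was 0.106, against 0.016 simulated from the shared arrays.

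Filgotinib against DSS vehicle and filgotinib with DSS against water share the filgotinib arrays. They shared 422 genes with the same sign, 268 higher and 154 lower, and 54 with opposite signs, against 130 for independent lists, and with the filgotinib arrays split 4 to 130 (median 25.5, against 9.3). Of the 422, 406 were not called in DSS against water, though a difference from the DSS effect was not tested. The covariance was 0.006, against 0.024 simulated from the shared arrays.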
